A study of Vigna radiata with 18 samples.

How the data were processed

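Whole-genome bisulfite libraries from leaf DNA of 18 mung bean samples, 3 in each of 6 groups, were analysed from the processed table of the series. The submitters' processing notes name fastp 1.0.1, Bismark 0.25.1, SAMtools 1.22.1, methylKit 1.34.0 and R 4.4.3, without the role of each. Per the labels' protocols, the libraries were made with the TruSeq DNA Methylation kit and sequenced from both ends of each fragment. The genome build, the trimming and mapping settings, the treatment of duplicate reads and the conversion rate are not given in the sources used here. The deposited table holds, for each library, whole-number counts of methylated CG calls and of all CG calls per window and strand, with no normalization by the authors visible in the values. It has 25481121 lines, only CG context, and no column names. That the smaller of the 2 counts is the methylated one was read from the values, which are low in the deepest windows and at chromosome ends and high in chromosome interiors. All window starts are spaced by multiples of 600 bp, and a window was taken to span 600 bp from its start; this length is inferred. Coordinates are those of the table.

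Each library was assigned to its group by its name. Counts of 1504156 strand windows and, with both strands summed, of 767067 windows were used, and those with at least 5 calls in all 18 libraries were tested: 1194144 strand windows and 664279 windows. The design had been fixed for single sites, 1 kb windows, gene bodies and promoters, and for gene lists. Single sites and 1 kb windows cannot be formed from 600 bp sums, so strand windows stood in for sites and windows with both strands for the 1 kb windows. The available gene table belongs to an assembly with other chromosome lengths, so gene features and gene lists were not analysed here. Contexts other than CG, and organelle sequences as a measure of conversion, were not used here; the mean level of windows below 5% was 2.46 to 2.64% in every library, which bounds the share of unconverted calls there from above.

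The genome-wide level of a library was computed as methylated over all calls pooled over tested windows, and as the mean of window levels. Its 95% Wilson interval had a half-width of 0.00778 to 0.0111 points, which covers counting error only, since calls on the same fragment are not independent. Groups were compared by exact two-sided permutation of libraries, 3 against 3, for which 0.1 is the smallest possible p, with Benjamini-Hochberg (BH) adjustment over the 7 comparisons, and over classes and comparisons for the classes of window level. A pooled difference was split, after it had been seen, into a part from the shares of calls per window, with window levels fixed at the mean of both groups, and a part from the levels with the shares fixed. Chromosome and 1 Mb values are means of window levels.

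Windows were tested with a quasi-binomial likelihood-ratio F test on methylated and total counts. The dispersion of each window came from all 6 groups, was moderated towards the common value as in limma (squeezeVar) and was not let below 1. The moderated prior was 1.43 for windows and 1.32 for strand windows, so that levels varied more than independent calls would; calls that share a fragment add to this. A window was called at a BH-adjusted p below 0.05 with a difference of pooled group levels of at least 10 points, and a strand window with at least 25 points. Levels are printed as the mean ± SD over libraries, so that a printed difference, taken from pooled calls, can deviate slightly from the difference of the means. The difference of responses was tested with limma on arcsine square root levels and called at an adjusted p below 0.05 with no minimum difference, as fixed in the design. The other limma counts use the minimum differences above unless stated. The test without overdispersion is a binomial likelihood-ratio test, close to a default of methylKit. The rule for the named windows, set before the data were examined, was the called windows with the largest differences and separate libraries in each comparison or, if none was called, the 3 with the smallest p, with strand windows named for T1_0h against T2_0h, T2_48h against T2_0h and T1_48h against T1_0h. The 4 windows of the difference of responses fell outside this rule and were named because their number was small.

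The test was checked on simulated counts with the real depths and dispersions, in which 200 windows each were changed by 10, 25 and 40 points. For T2_48h against T2_0h it called 7, 57.5 and 91% of them and 8 of the unchanged windows, where the binomial test called 2487 unchanged windows. For T1_0h against T2_0h it called 6, 47 and 80.5% and 12 unchanged windows. In the real libraries of T2_48h and T2_0h the binomial test called 6198 windows. It called 6324 to 8798 when the same 6 libraries were divided otherwise. The simulated libraries therefore seem to vary less than the real ones, and the shares called may be too high. The limma-type fit, written in Python, was tested on simulated data against limma 3.58.1 in R 4.3.3. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

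Alternatives were other coverage minimums (1, 10 and, for the difference of responses, 20 calls), other minimum differences, the binomial test, limma, limma with each library centred, replicate number as a block, a fit of only the 2 groups compared, thinning to the depth of the shallowest library, each replicate left out, windows of 1.2 kb and bins of 60 kb. Windows variable between libraries, regardless of group, were those with at least 20 calls in every library, a dispersion above 8 and a range of at least 50 points. Resemblance between libraries was tested by permuting libraries 100000 times.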

Results

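CG methylation was measured by whole-genome bisulfite sequencing in leaves of mung bean (Vigna radiata, a grain legume) of the cultivar Weilv 9. Bisulfite treatment converts unmethylated cytosine, so that the share of unconverted calls at CG positions gives the methylation level. Seedlings of treatment T1 had a first salt exposure (NaCl at 100 mM) that lasted 24 h. They recovered for 48 h in salt-free nutrient solution and then met the same salt concentration again. Seedlings of treatment T2 met this concentration with no earlier exposure. Leaves were taken at 0, 6 and 48 h of the final salt exposure, which gave 6 groups of 3 libraries, named T1_0h, T1_6h, T1_48h, T2_0h, T2_6h and T2_48h. T2_0h stands for leaves with no salt exposure and served as the control, and T1_0h for leaves after the first exposure and the recovery. The libraries held 78507854 to 159253642 CG calls. The deepest were replicates 2 and 3 of T2_48h with 159253642 and 148104634. Calls were given in windows of 600 bp on 11 chromosomes, and 664279 windows had at least 5 calls in every library. The labels call the replicates biological, but which plants went into each library is not given in the sources used here, so that p-values measure only the spread between these libraries.

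The leaf methylome was close to an on-off landscape. Of the 664279 windows, 257360 (38.7%) had a level below 5% over all libraries and 244233 (36.8%) a level of 95% or more, while only 58691 (8.84%) lay between 20 and 80%. Chromosome ends were weakly methylated and interiors heavily methylated on most chromosomes. Since this direction was used to tell which count is the methylated one, it is not an independent finding. The lowest 1 Mb bin was on chromosome 11 (1000001 to 2000000) at 8.88%, and the highest on chromosome 2 (17000001 to 18000000) at 95.2%. Chromosome 11 differed in shape, since its highest bin, at 92.9%, lay near its far end (35000001 to 36000000). Chromosome 9 had the highest mean level (60.2%, libraries from 59.99 to 60.29%). Chromosomes 7 and 6 had the lowest, 47.76 and 47.79%, with libraries from 47.6 to 47.88% and from 47.58 to 47.95%. In legume genomes the chromosome arms generally hold most genes and the interiors most repeats, but no gene positions on the genome build of these coordinates were used here, so genes, exons and promoters are not assigned to windows.

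**Figure D1:**
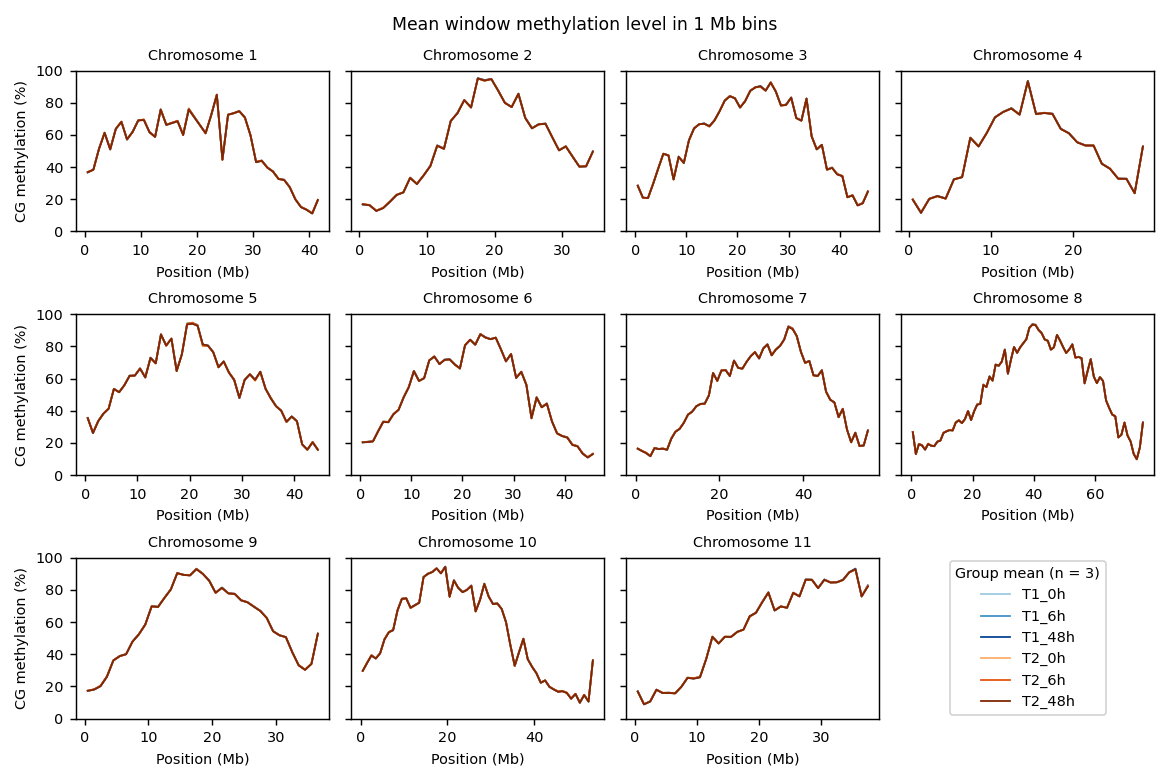
Mean CG methylation level (%) of 600 bp windows in 1 Mb bins along each of the 11 chromosomes (position in Mb), with a line for the mean of each group (n = 3). The 6 lines lie on top of each other and run from 8.88% in the lowest bin to 95.2% in the highest.

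Before the final salt exposure, leaves that had been preconditioned and had recovered (T1_0h) were compared with leaves never exposed (T2_0h), which asks what the first exposure left behind. The mean window level was 51.6% ± 0.0552 in T1_0h and 51.6% ± 0.108 in T2_0h (SD, n = 3 each), a difference of 0.0874 points (exact two-sided permutation p = 0.3, BH-adjusted p = 0.9 over 7 comparisons). It was 0.0324 without T2_0h replicate 1 and 0.141 without T2_0h replicate 3. With all calls pooled the levels were 54.4% ± 0.881 and 54.3% ± 0.571, a difference of 0.128 points (exact p = 1). The pooled difference turned negative without T1_0h replicate 1. All 11 chromosomes were higher in T1_0h, by 0.0632 to 0.11 points. Chromosomes of the same library are not independent, and in 4 of the other 6 comparisons all 11 also moved one way, higher in T1_48h than in T2_48h and in T2_6h than in T2_0h, and lower in T1_6h than in T1_0h and in T2_48h than in T2_0h. Windows below 5% had a mean level of 2.53% ± 0.0525 in T1_0h and 2.58% ± 0.0306 in T2_0h, and windows of 95% or more had 96.8% ± 0.0937 and 96.7% ± 0.0617 (SD, n = 3; exact p = 0.3 for both).

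No window passed the test between T1_0h and T2_0h, and the windows with the smallest p are given as not passing. The window on chromosome 11 (24757801 to 24758400) had a level of 27.8% ± 1.18 in T1_0h and 45.3% ± 5.1 in T2_0h (SD, n = 3, 170 to 289 calls per library; quasi-binomial adjusted p = 0.908). On chromosome 7 (48850201 to 48850800) the levels were 12.1% ± 5.35 and 1.49% ± 1.91, and on chromosome 9 (4650601 to 4651200) 27.1% ± 13.1 and 5.21% ± 2.98, with the same adjusted p. Among windows of a single strand, the smallest p values belonged to the plus strand of chromosome 10 (8442601 to 8443200), chromosome 5 (2269801 to 2270400) and chromosome 7 (6516001 to 6516600), with differences of 11.03, 17.14 and -26.58 points, T1_0h minus T2_0h (adjusted p = 0.801 for each). That on chromosome 5 had 22.25 points without T2_0h replicate 2 (adjusted p = 0.01), below the minimum of 25 points, and 12.5 points without T2_0h replicate 1 (0.821). The binomial test also gave it a low p, and the other alternatives gave adjusted p up to 0.925. The quasi-binomial test called 0 of 664279 windows at a minimum difference of 10 points, with 36497 (5.49%) at an unadjusted p below 0.05. limma called 0 at this minimum and 5 without it, and a binomial test without overdispersion called 5375. On single strands it called 0 of 1194144, with 74481 below an unadjusted 0.05. limma called 0 and the binomial test 1545. In data simulated for this comparison, 47% of the windows changed by 25 points and 6% of those changed by 10 points were called. The simulated change of 10 points equalled the minimum difference, and 61% of these windows had an unadjusted quasi-binomial p below 0.05. The adjusted p also depends on how many windows change, here 200 of each size. These shares therefore hold for the simulated windows, and whether they carry over to other windows was not tested. They may be too high, since the binomial test called 2792 unchanged windows in the simulated data and 5375 windows in the real data. That 0 windows were called does not exclude local changes of 10 points.

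In plants exposed to salt directly, the comparison asks how methylation changed during the exposure. None of the groups holds unexposed plants at 6 or 48 h, so salt cannot be told apart from time, here and in T1. After 6 h (T2_6h) the mean window level was 51.6% ± 0.0915, against 51.6% ± 0.108 in T2_0h (SD, n = 3 each), a difference of 0.0545 points (exact two-sided permutation p = 0.6). That difference turned to -0.000538 without T2_0h replicate 1. After 48 h (T2_48h) the mean window level was 51.5% ± 0.0907, a difference from T2_0h of -0.0428 points (exact p = 0.7) that turned to 0.0104 without T2_0h replicate 3 and to 0.00489 without T2_48h replicate 3. The pooled level behaved otherwise: it was 53% ± 0.214 in T2_48h and 54.3% ± 0.571 in T2_0h, with every T2_48h library below every T2_0h library, a difference of -1.3 points (exact p = 0.1, the smallest that 3 against 3 libraries allow; BH-adjusted p = 0.35). Replicates 2 and 3 of T2_48h were also the deepest libraries. The share of calls that fell in windows below 5% was 39.2% ± 0.208 in T2_48h and 37.8% ± 0.647 in T2_0h (exact p = 0.1, BH-adjusted p = 0.5), and the share in windows of 95% or more was 41.3% ± 0.169 and 42.4% ± 0.464. The levels within these classes differed by -0.0351 points below 5% and -0.0121 points at 95% or more (exact p = 0.5 and 0.6). At 6 h the pooled level of T2 was 53.9% ± 1.44, a difference from T2_0h of -0.328 points (exact p = 0.8).

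**Figure D2:**
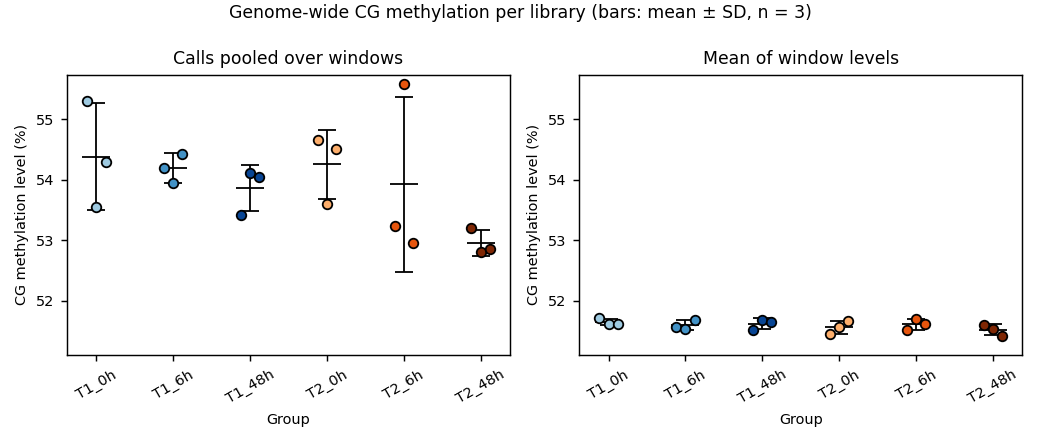
CG methylation level (%) of each library by group, from calls pooled over windows (left) and as the mean of window levels (right), with bars for the mean ± SD (n = 3). The pooled level of T2_48h (53% ± 0.214) lies below that of T2_0h (54.3% ± 0.571), while the mean window levels of both groups are 51.5% ± 0.0907 and 51.6% ± 0.108.

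A window on chromosome 8 (70779001 to 70779600) had the smallest p between T2_48h and T2_0h with both strands summed. On its plus strand the level was 94.3% ± 2.41 in T2_48h and 64.5% ± 5.78 in T2_0h (SD, n = 3, 111 to 287 calls per library). All 3 T2_48h libraries lay above all 3 T2_0h libraries, and the pooled group levels differed by 30.1 points. It was the only strand window called (quasi-binomial adjusted p = 0.0431). With both strands the levels were 92.5% ± 3.06 and 64.2% ± 5.82, which did not pass (adjusted p = 0.202). Libraries of the other groups ranged from 75.6 to 97.01% in T1_0h and from 69.45 to 76.46% in T1_6h. They ranged from 67.09 to 85.38% in T1_48h and from 64.75 to 78.93% in T2_6h. The call ended with limma (adjusted p = 0.622), when only these 2 groups were fitted (0.923) and in each fit that left out 1 library (0.067 to 0.368) except that without T2_0h replicate 2 (0.0407). Over all alternatives except the binomial test the adjusted p ran from 0.00523 to 0.923. Another window on chromosome 8 (62590801 to 62591400) had 83.8% ± 11.1 in T2_48h and 97.2% ± 0.645 in T2_0h (269 to 902 calls, adjusted p = 0.202). It passed without T2_48h replicate 1 (adjusted p = 0.00784) or replicate 3 (0.00575), and the adjusted p of its other alternatives reached 1. On its minus strand alone the difference was -17.7 points (adjusted p = 0.0156), below the minimum of 25 points; this strand was singled out after its values were seen. The window on chromosome 3 (42988201 to 42988800) had 3.56% ± 0.341 in T2_48h and 13.0% ± 1.79 in T2_0h (262 to 577 calls, adjusted p = 0.266).

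Between T2_48h and T2_0h the quasi-binomial test called 0 windows, with 38785 (5.84%) at an unadjusted p below 0.05. limma called 0 and the binomial test without overdispersion 6198, of which 2947 were higher and 3251 lower. In data simulated for this comparison 57.5% of the windows changed by 25 points were called. Between T2_6h and T2_0h it called 0 windows and 0 strand windows, with 37095 and 74422 at an unadjusted p below 0.05. limma called 0 and 0, and the binomial test 5764 and 1403. The smallest p at 6 h belonged to a window on chromosome 11 (5398201 to 5398800) with 2.09% ± 0.358 in T2_6h and 11.03% ± 2.91 in T2_0h (SD, n = 3, 160 to 219 calls per library). Next came a window on chromosome 8 (64956601 to 64957200) with 79.8% ± 4.46 and 45% ± 11.1, and a window on chromosome 10 (50799001 to 50799600) with 0.422% ± 0.366 and 6.84% ± 1.77. None of these passed (quasi-binomial adjusted p = 0.893 for each).

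For preconditioned plants the comparison asks how methylation moved during the second exposure. The mean window level was 51.6% ± 0.0552 in T1_0h, 51.6% ± 0.0787 in T1_6h and 51.6% ± 0.0911 in T1_48h (SD, n = 3 each), with differences from T1_0h of -0.049 points at 6 h and -0.0305 points at 48 h (exact two-sided permutation p = 0.4 and 0.8). The difference at 6 h was -0.0172 without T1_0h replicate 1 and -0.0933 without T1_6h replicate 3, and that at 48 h turned to 0.0208 without T1_48h replicate 1. The pooled levels were 54.4% ± 0.881, 54.2% ± 0.246 and 53.9% ± 0.385, with differences of -0.192 and -0.521 points (exact p = 0.8 and 0.4). Without T1_0h replicate 1 the latter was -0.0609 points and the former 0.268. Windows between 20 and 80% had a mean level of 51.6% ± 0.0496 in T1_0h and 51.1% ± 0.196 in T1_6h, a difference of -0.483 points with no overlap between the libraries (exact p = 0.1, BH-adjusted p = 0.955 over the classes and comparisons), and 51.2% ± 0.423 in T1_48h.

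Between T1_48h and T1_0h, the window on chromosome 6 (4169401 to 4170000) had 24.2% ± 5.78 and 47.6% ± 1.62 (SD, n = 3, 158 to 223 calls per library). The window on chromosome 3 (14849401 to 14850000) had 90.5% ± 2.86 and 67.3% ± 5.67, and that on chromosome 11 (11753401 to 11754000) 1.24% ± 0.437 and 11.8% ± 7.92. None of them passed (quasi-binomial adjusted p = 0.319 for each), although the window on chromosome 11 passed without T1_0h replicate 1 (adjusted p = 0.0115, against 0.935 when only these 2 groups were fitted). The strand windows with the smallest p were on the plus strand of chromosome 7 (5136601 to 5137200) and of chromosome 6 (27860401 to 27861000) and on the minus strand of chromosome 1 (36571201 to 36571800), with differences of 22.2, -41.8 and -33.7 points, T1_48h minus T1_0h (adjusted p = 0.592 for each). That on chromosome 7 passed without T1_0h replicate 1, with a difference of 27.6 points (adjusted p = 0.0443, against 0.92 when only these 2 groups were fitted). Between T1_6h and T1_0h, the window on chromosome 8 (12110401 to 12111000) had 99.8% ± 0.365 and 90.4% ± 2.78. That on chromosome 3 (43861801 to 43862400) had 17.2% ± 1.45 and 0.23% ± 0.398, and that on chromosome 1 (39579601 to 39580200) 31.5% ± 3.16 and 52.2% ± 3.94 (adjusted p = 0.633 for each). The quasi-binomial test called 0 windows and 0 strand windows at both times. At 6 h 36792 windows and 73887 strand windows had an unadjusted p below 0.05, limma called 0 and 0, and the binomial test 5813 and 1508. At 48 h 36714 and 74336 had an unadjusted p below 0.05, limma called 0 and 0, and the binomial test 5725 and 1606. In data simulated for T1_48h against T1_0h, 51.5% of the windows changed by 25 points were called.

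The treatments were then compared at the same time after the onset of the final exposure. At 6 h the mean window level was 51.6% ± 0.0787 in T1_6h and 51.6% ± 0.0915 in T2_6h (SD, n = 3 each), a difference of -0.0161 points (exact two-sided permutation p = 0.9). That difference turned to 0.0148 without T1_6h replicate 2 and to 0.0281 without T2_6h replicate 2. At 48 h the mean window level was 51.6% ± 0.0911 in T1_48h and 51.5% ± 0.0907 in T2_48h, a difference of 0.0997 points (exact p = 0.3), with all 11 chromosomes higher in T1_48h by 0.0674 to 0.121 points. It was 0.052 without T2_48h replicate 3 and 0.151 without T1_48h replicate 1. The pooled level was 53.9% ± 0.385 in T1_48h and 53% ± 0.214 in T2_48h, a difference of 0.904 points with no overlap between the libraries (exact p = 0.1, BH-adjusted p = 0.35). The different shares of calls between windows gave 0.811 of these points and the levels of the windows 0.0912. The share of calls in windows below 5% was 38.3% ± 0.231 in T1_48h and 39.2% ± 0.208 in T2_48h (SD, n = 3; exact p = 0.1, BH-adjusted p = 0.5).

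At 6 h the window on chromosome 8 (69990001 to 69990600) had 52.6% ± 4.09 in T1_6h and 73.6% ± 2.55 in T2_6h (SD, n = 3, 207 to 308 calls per library), which did not pass (quasi-binomial adjusted p = 0.115). The window on chromosome 11 that led the T2 comparison at 6 h (5398201 to 5398800) had 13.0% ± 2.6 in T1_6h and 2.09% ± 0.358 in T2_6h (adjusted p = 0.162), and a window on chromosome 8 (16776001 to 16776600) 79.4% ± 6.79 and 50.5% ± 2.65 (adjusted p = 0.315). At 48 h the window on chromosome 8 (62590801 to 62591400) had 97.5% ± 1.2 in T1_48h and 83.8% ± 11.1 in T2_48h (adjusted p = 0.353). It passed without T2_48h replicate 1 (adjusted p = 0.0139) or replicate 3 (0.00787), with other alternatives up to 1. Its minus strand, singled out after its values were seen, differed by 19.1 points (adjusted p = 0.00155), below the minimum of 25 points. The windows at 5398201 and 62590801 share their T2_6h or T2_48h libraries with the comparisons within T2 that name them. A window on chromosome 1 (31438801 to 31439400) had 22% ± 8.81 in T1_48h and 70.2% ± 12.6 in T2_48h with 13 to 70 calls per library, and one on chromosome 6 (6886801 to 6887400) 35.4% ± 9.76 and 10.4% ± 3.49 (adjusted p = 0.741 for both). The quasi-binomial test called 0 windows and 0 strand windows at both times. At 6 h 37697 and 74737 had an unadjusted p below 0.05, limma called 0 and 0, and the binomial test 6902 and 1632. At 48 h 38151 and 75036 had an unadjusted p below 0.05, limma called 0 and 0, and the binomial test 6050 and 1224.

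**Figure D3:**
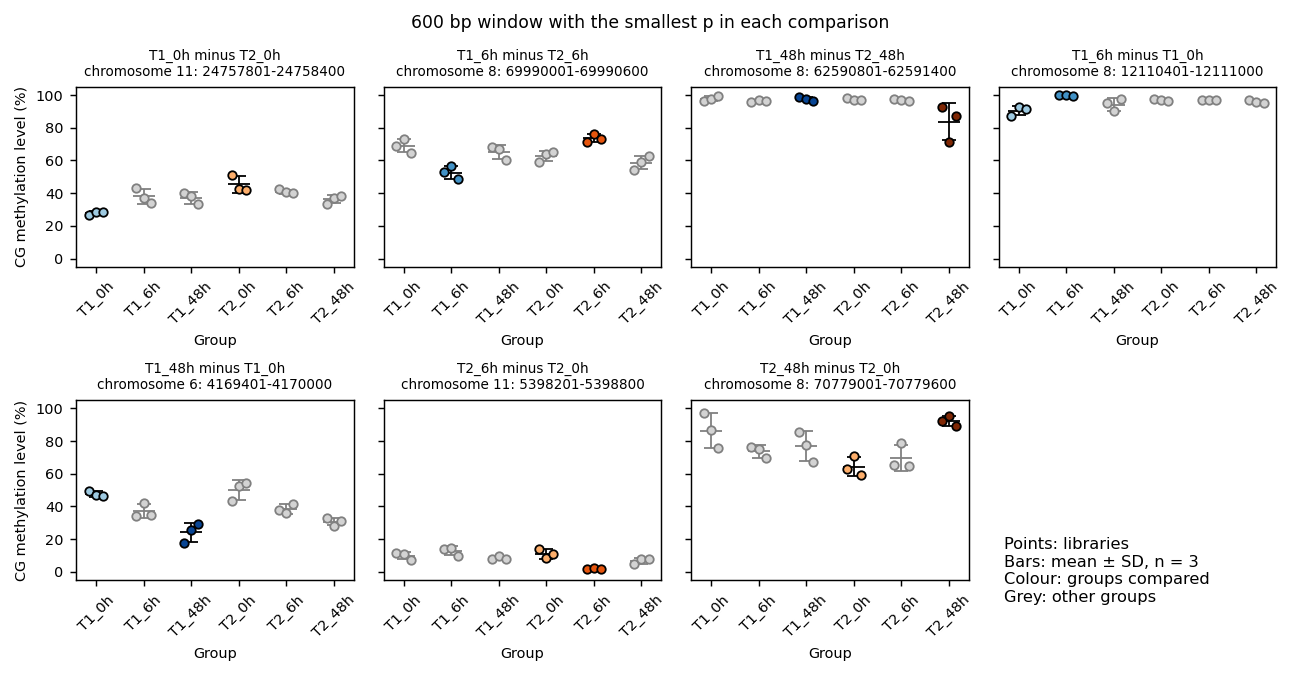
CG methylation level (%) of each library by group in the 600 bp window with the smallest p of each of the 7 comparisons, with bars for the mean ± SD (n = 3), the compared groups in colour and the other groups in grey. On chromosome 8 (70779001 to 70779600) T2_48h stands at 92.5% ± 3.06 and T2_0h at 64.2% ± 5.82, and none of the windows shown passed the test with both strands.

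Whether the response to salt differed between preconditioned and directly exposed plants was tested as the difference of the changes from 0 h, at an adjusted p below 0.05 with no minimum difference. At 6 h limma called 2 windows. On chromosome 1 (3976201 to 3976800) the change in T1 minus the change in T2 was -23.9 points (SE 6.01, adjusted p = 0.042), and on chromosome 8 (28551001 to 28551600) -9.05 points (SE 0.952, adjusted p = 0.042). At 48 h it called 4 windows. The same pair was at -24.1 points (SE 5.81, adjusted p = 0.028) and -9.05 points (SE 0.952, adjusted p = 0.028). The others were on chromosome 3 (23941801 to 23942400) at -17.2 points (SE 1.87, adjusted p = 0.0367) and chromosome 8 (11652601 to 11653200) at 10.2 points (SE 2.18, adjusted p = 0.028). The windows on chromosome 1 and on chromosome 8 at 28551001 shared their low group, T2_0h, with 82.9% ± 9.94 and 91.0% ± 1.65 (SD, n = 3) against 93 to 100% in the other groups of the test. Depth was low, with 9 to 58 calls per library, and groups at 0% or 100% had an SD of 0. None of the 4 windows passed on the percent scale, with replicate number as a block, or in any fit that left out a replicate (adjusted p from 0.121 to 0.982). With at least 20 calls per library 0 windows were called at either time. That minimum removed the 4 windows before testing, so it is no test of them. At an unadjusted p below 0.05 there were 35534 windows at 6 h and 32299 at 48 h.

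The numbers called by the binomial test, which treats all calls as independent, were set beside those from the other ways to divide the same 6 libraries into 3 and 3. For T2_48h against T2_0h the study groups gave 6198 windows and the other divisions 6324 to 8798. For T1_0h against T2_0h they gave 5375 and the others 5066 to 8833, and for T1_6h against T2_6h 6902 and 5897 to 8856. In 4 of the 7 comparisons the study groups gave fewer windows than every other division.

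**Figure D4:**
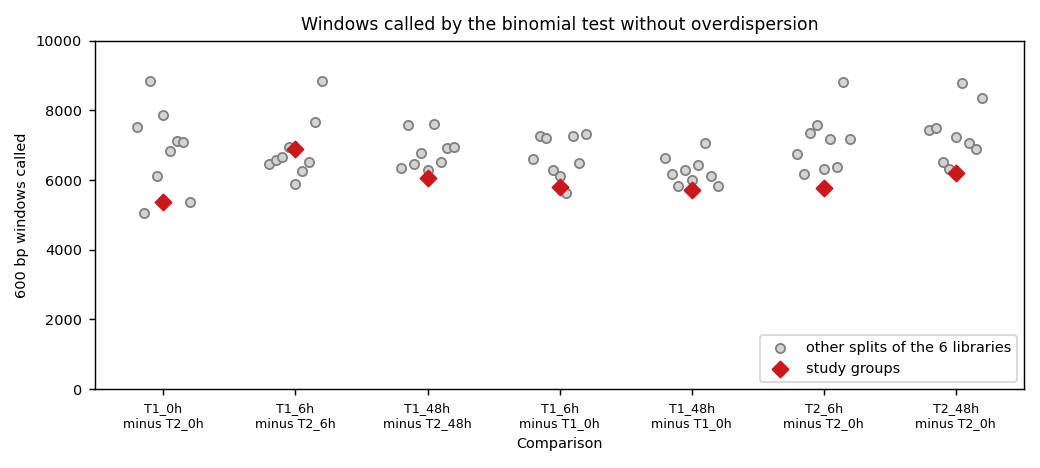
Number of 600 bp windows called by the binomial test without overdispersion (vertical axis) in each of the 7 comparisons, for the study groups (diamonds) and the other divisions of the same 6 libraries (circles). In every comparison another division gave at least as many windows, with the highest at 8856.

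With at least 20 calls in every library, 172812 of 582174 windows (29.7%) varied more over the 18 libraries than independent calls would, to which calls that share a fragment can add, and 1496 (0.257%) had a dispersion above 8 and a range of at least 50 points. Resemblance at these windows did not follow the groups. Across windows, which are not independent replicates, Pearson's r averaged -0.116 between libraries of the same group and -0.0506 between libraries of different groups (permutation p = 0.148). Each window's mean over the libraries was taken away first, which by itself makes the average r slightly negative. The closest pairs were replicate 3 of T2_0h with replicate 3 of T1_6h (r = 0.416) and replicate 1 of T2_0h with replicate 1 of T1_6h (r = 0.411), then replicate 2 of T2_6h with replicate 2 of T2_0h (r = 0.301). These 3 pairs share a replicate number and the next, replicate 2 of T2_48h with replicate 1 of T1_6h (r = 0.29), does not.

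**Figure D5:**
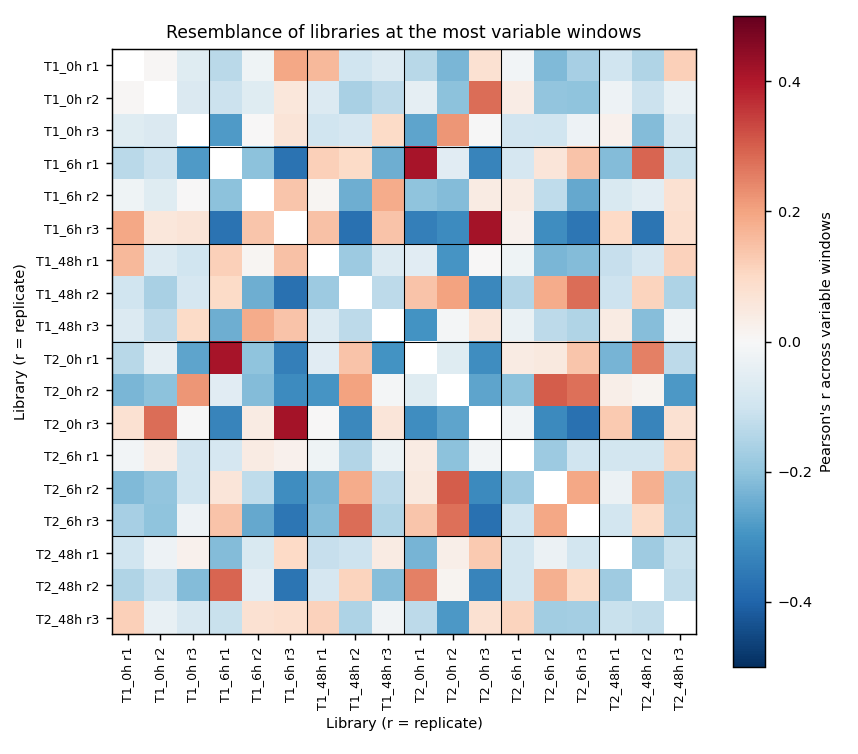
Pearson's r between libraries (both axes, ordered by group, lines between groups) across the 1496 most variable windows, after each window's mean was taken away. The strongest positive values, 0.416 and 0.411, join libraries of T2_0h and T1_6h, and no block of high values appears within the groups.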

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

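The tests by other divisions of the libraries were set after the data were examined and before their counts were seen. In 4 windows the change during salt exposure differed between preconditioned and directly exposed plants by a test of the difference itself. On chromosome 1 (3976201 to 3976800) the change in T1 minus that in T2 was -23.9 points at 6 h and -24.1 points at 48 h. T2_0h was at 82.9% ± 9.94, T2_6h and T2_48h at 100%, T1_0h at 100%, T1_6h at 93.2% ± 3.12 and T1_48h at 93% ± 1.58 (SD, n = 3). On chromosome 8 (28551001 to 28551600) it was -9.05 points at both times, since T2_0h had 91.0% ± 1.65 and the other groups 100%. On chromosome 3 (23941801 to 23942400) it was -17.2 points at 48 h, with T1_0h at 11.2% ± 2.12, T1_48h at 0%, T2_0h at 0% and T2_48h at 6.05% ± 2.44. On chromosome 8 (11652601 to 11653200) it was 10.2 points at 48 h, with T1_0h at 93.2% ± 2.84, T1_48h at 100%, T2_0h at 100% and T2_48h at 96.6% ± 2.48. These windows held 9 to 58 calls per library. In 40 random assignments of the 12 libraries, the real included, 27 gave at least the 2 windows called at 6 h (highest other 12). For the 4 windows at 48 h it was 12 of 40 (highest other 14), so chance cannot be excluded at either time. Of 36 pairs of a genome-wide, class or chromosome level and a time, none had all T1 libraries moving one way and all T2 libraries the other.

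For the pairwise comparisons there are only 10 divisions of 6 libraries, too few for a share under 0.05. Between T2_48h and T2_0h the study groups gave 1 strand window and the highest other division 7, and 4 of the 10 gave at least 1. For strand windows in the other 6 comparisons the study groups gave 0, so that all 10 divisions gave at least as many. The highest other was at 0 for T1_0h against T2_0h, 1 for T1_6h against T2_6h, 3 for T1_48h against T2_48h, 0 for T1_6h against T1_0h, 1 for T1_48h against T1_0h and 1 for T2_6h against T2_0h. For windows with both strands the study groups gave 0 throughout, and the highest other division gave 0, 0, 3, 0, 1, 0 and 8 in the order T1_0h, T1_6h and T1_48h against T2 at the same time, T1_6h and T1_48h against T1_0h, and T2_6h and T2_48h against T2_0h. The 8 windows came from the division with T2_48h replicate 1 and T2_0h replicates 2 and 3 on one side and both deep T2_48h libraries with T2_0h replicate 1 on the other.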

How the results depend on the processing

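Bins, 1.2 kb windows, the binomial and thinned runs on windows and the minimum of 20 calls were chosen after seeing the data. The cause of a change was not tested unless stated. The binomial test gave 1545, 1632, 1224, 1508, 1606, 1403 and 1322 strand windows and 5375, 6902, 6050, 5813, 5725, 5764 and 6198 windows, in the order T1_0h, T1_6h and T1_48h against T2 at the same time, T1_6h and T1_48h against T1_0h, T2_6h and T2_48h against T2_0h. The single strand window of T2_48h against T2_0h became 0 with only the 2 groups fitted, limma, centred limma, the replicate block, a minimum of 1 call or thinning. It stayed 1 with at least 10 calls and became 2 with a minimum difference of 10 points or none, where T1_48h against T2_48h gave 1. Without a replicate strand windows ranged from 0 to 2 for T2_48h against T2_0h (0 without T2_0h replicate 1 or T2_48h replicate 2, 2 without T2_0h replicate 2 or T2_48h replicate 3). The window at 70779001 itself passed only without T2_0h replicate 2 (adjusted p = 0.0407). Strand windows ranged from 0 to 1 for T1_48h against T1_0h (1 without T1_0h replicate 1) and from 0 to 1 for T1_48h against T2_48h (1 without T2_48h replicate 3).

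With a minimum of 10 points windows stayed at 0 in all comparisons with only the 2 groups fitted, limma, the block, at least 1 or 10 calls, thinning and 1.2 kb windows. The quasi-binomial test also gave 0 with no minimum, where limma gave 5, 1, 4, 0, 1, 2 and 4 windows and 2, 1, 2, 3, 0, 1 and 3 strand windows in the order above. Centred limma gave 1 for T1_0h against T2_0h, and limma on the mean of strand levels gave 2, 1, 2, 2, 1, 1 and 3 in the order above. Bins of 60 kb were called with no minimum difference. Those of mean levels gave 0 in all comparisons. Pooled bins gave 14 for T2_48h against T2_0h, 8 higher and 6 lower, and 0 elsewhere. They covered 8248 bins and the mean levels 7744, and the cause of the 14 was not tested. Without a replicate windows ranged from 0 to 1 for T1_0h against T2_0h (1 without T2_0h replicate 3), T1_48h against T1_0h (1 without T1_0h replicate 1) and T2_6h against T2_0h (1 without T2_0h replicate 1 or 3). They ranged from 0 to 2 for T1_48h against T2_48h (2 without T2_48h replicate 1 or 3) and from 0 to 3 for T2_48h against T2_0h (1 without T2_0h replicate 2, 2 without T2_0h replicate 3 or T2_48h replicate 1, 3 without T2_48h replicate 3). Of 421 values of named windows under an alternative, 354 kept their side, 41 no longer passed, 26 newly passed (most of them by the binomial test) and 0 reversed, though several alternatives change the test and not the difference itself. This tally does not show stable calls, since most of the 354 passed neither in the main fit nor in the alternative. The 41 all belong to the only named windows that passed in the main fit. These were the strand window at 70779001 and the 4 windows of the difference of responses.

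The difference of responses became 0 at 6 h and 48 h with the replicate block, on the percent scale and with at least 20 calls, and ranged from 0 to 3 at 6 h and from 0 to 1 at 48 h without a replicate number (0 without number 1 or 3 at both times). Replicate numbers were not taken to pair libraries, since none of the 45 same-number pairs reached the correlation of deviations of 0.1 set beforehand (-0.0343 to 0.0643 over all windows). None of the 90 pairs with different numbers reached it either (-0.0629 to 0.0488). The check therefore could hardly be passed and cannot exclude a pairing. Of 18 libraries, 6 were closest to their own number. Against limma without it, the block changed no call between 2 groups, since the strand window of T2_48h against T2_0h was already lost with limma alone (adjusted p = 0.622, and 0.866 with the block). The pooled difference turned to -0.0161 points for T1_6h against T2_6h and to 0.0545 for T2_6h against T2_0h as the mean of window levels. Without a replicate it ranged from -0.332 to 0.546 points for T1_0h against T2_0h, from -0.222 to 1.09 for T1_6h against T2_6h, from -0.61 to 0.268 for T1_6h against T1_0h and from -1.16 to 0.158 for T2_6h against T2_0h. For T1_48h against T1_0h it ranged from -0.939 to -0.0609 (the latter without T1_0h replicate 1). The difference of mean window levels, left out in the same way after seeing the data, turned for T2_48h against T2_0h (0.0104 without T2_0h replicate 3, 0.00489 without T2_48h replicate 3), T1_48h against T1_0h (0.0208 without T1_48h replicate 1, 0.00123 without T1_0h replicate 1), T1_6h against T2_6h (0.0148 without T1_6h replicate 2, 0.0281 without T2_6h replicate 2) and T2_6h against T2_0h (-0.000538 without T2_0h replicate 1). It ranged from 0.0324 (without T2_0h replicate 1) to 0.141 (without T2_0h replicate 3) for T1_0h against T2_0h, from 0.052 (without T2_48h replicate 3) to 0.151 (without T1_48h replicate 1) for T1_48h against T2_48h and from -0.0933 (without T1_6h replicate 3) to -0.0172 (without T1_0h replicate 1) for T1_6h against T1_0h. Windows of 500 bp, gene features, 1 kb promoters and gene lists were not run. Depth limits the 4 windows of the difference of responses, whose shallowest libraries had 9 to 12 calls, so that the minimum of 20 calls removed them before testing.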

Other observations

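The tests of the pooled level, and of resemblance between libraries by noise, group, replicate number and distance, were chosen after the result was seen. The binomial test on windows was also added after seeing the data, and its other divisions were set once its counts were known. Some of the most variable windows ranged from no to full methylation between single libraries. On chromosome 5 (18719401 to 18720000) the level was 0% in T2_0h replicate 1 and 100% in T1_6h replicate 3, with 24 to 54 calls per library, and on chromosome 6 (10792201 to 10792800) it was 0% in T1_48h replicate 2 and 100% in T1_0h replicate 2. Chromosome 5 had the highest rate of such windows, 4.14 per 1000 windows, and chromosome 3 the lowest, 1.86 per 1000. Directly adjoining variable windows deviated together (mean r = 0.586 over 78 pairs of windows), windows above 600 bp and up to 2.4 kb apart less (0.142 over 38 pairs), and windows 2.4 to 10 kb apart had a mean r of -0.0318 over 75 pairs.

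A small set of very deep windows was weakly methylated, a direction that was also used to tell which count is the methylated one. The 604 windows with a median above 1000 calls took 1.03 to 1.45% of the calls and had a level of 11.2 to 13.2%. Chromosome 11 held 135 of them and chromosome 9 the fewest, 22. The deepest, on chromosome 7 (40015801 to 40016400), had a median of 11326 calls and 1.74 to 2.29% methylation in the 18 libraries. The highest count in a strand window lay between 5781 and 6033 in every library, although total calls ranged from 78507854 to 159253642. Whether a depth limit was applied upstream is not given in the sources used here, and with such a limit the counts and call shares of the deepest windows would be lower bounds.

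The pooled methylation level differed between T2_48h and T2_0h by -1.3 points with no overlap of libraries, and the mean window level by -0.0428 points (exact p = 0.7), with a sign that turned without T2_0h replicate 3 or T2_48h replicate 3. With window levels held fixed, the different shares of calls between weakly and heavily methylated windows gave -1.25 points of the difference, and with the shares held fixed, the levels gave -0.0497 points. Windows below 5% differed by -0.0351 points, far less than a difference in bisulfite conversion of that size would need. The lower pooled level may therefore come from where the calls of the T2_48h libraries fell rather than from a loss of methylation. What moved the calls stays open. T2_48h holds the deepest libraries, but its replicate 1, with 94250145 calls, was also low at 53.2%. T2_6h replicates 1 and 3, with 91313071 and 93292453 calls, were at 53.24 and 52.95%, while T2_6h replicate 2, with 90757238 calls, was at 55.6%. T1_48h replicate 1, with 78507854 calls, was at 53.4%, and T1_6h replicate 3, with 112399650 calls, at 54.4%. Base composition was not analysed here.

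Many windows were called by the binomial test in every comparison. Another division of the same libraries gave as many in 7 of 7 comparisons, and the study groups reached 1.5 times the highest other division in 0 of 7. This argues only against a shared group effect in so many windows that the study groups would stand well above every other division. An effect in fewer windows could not be seen this way, since every division already gave many calls. Variation beyond that of independent calls could give such counts. Part of it could arise within a library, since calls on the same fragment depend on each other. In 4 of the 7 comparisons, which share libraries, the study groups gave fewer windows than every other division, and the cause was not tested. With 10 divisions no share under 0.05 is possible. T1_0h against T2_0h gave 5375 windows (highest other 8833, 9 of 10 at least as many), T1_6h against T2_6h 6902 (8856, 4 of 10) and T1_48h against T2_48h 6050 (7624, 10 of 10). T1_6h against T1_0h gave 5813 (7328, 9 of 10), T1_48h against T1_0h 5725 (7057, 10 of 10). T2_6h against T2_0h gave 5764 (8814, 10 of 10) and T2_48h against T2_0h 6198 (8798, 10 of 10). A local effect of salt or preconditioning that is smaller than this variation, or that covers fewer windows, stays open.

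Some pairs of libraries from different groups resembled each other at the variable windows (r up to 0.416), and others were opposed (r down to -0.375). The mean r of pairs from different groups was -0.0506, where taking away each window's mean by itself makes the average slightly negative. Noise of single windows is argued against by the agreement between chromosomes: resemblance on odd and on even chromosomes correlated at 0.926 over pairs of libraries (permutation p = 1e-05, the smallest 100000 permutations can give). Same-group pairs were not closer than others (difference of mean r -0.0651, permutation p = 0.148), and resemblance did not follow total calls (Mantel r = -0.0475) or the share of calls in weakly methylated windows (-0.0948). For a shared replicate number the difference was 0.0481 (permutation p = 0.097), which leaves it undecided. Variable windows 10 kb to 1 Mb apart had a mean squared correlation 0.00337 above that of windows on different chromosomes. This mean runs over all such pairs, so it cannot show whether a part of the windows lies in long linked blocks of sequence variants.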
